A study of Prunus persica with 24 samples.

How the data were processed

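RNA of peach (Prunus persica) fruit flesh was sequenced during storage at 25 or 35 °C after harvest. The labels list 24 libraries in 12 groups, 2 libraries for each temperature on days 1, 2, 3, 5, 6 and 7. Before that, the fruit had been kept at 5 °C for 2 days. Per the labels' protocols, ribosomal RNA was removed from total RNA and strand-specific libraries were sequenced on an Illumina instrument.

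The authors deposited FPKM values (fragments per kilobase of transcript, relative to all mapped fragments) in 2 tables, one per temperature. Each table holds 6 value columns, one for each day, and no column name carries a replicate number. The 2 libraries of a group therefore stand as 1 value, and how they were combined is not given in the sources used here. Tools named in the submitters' processing notes are FastQC 0.10.1, Bowtie2 2.1.0, TopHat2 2.0.10, SAMtools 0.1.18 and Cufflinks 2.1.1, without their roles. The genome build, the annotation and any scaling between columns are not given in the sources used here. The number of reads behind a column is unknown, so no counting interval or detection limit can be given. Transcript lengths are not given in the sources used here, and read numbers were not recovered from the low values. The FPKM of a column summed to between 651850 and 882184.

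Both tables list the same 29300 rows in the same order, for 26873 gene identifiers, and 2034 identifiers have more than 1 row. FPKM of rows with one identifier were summed. All 12 columns were then rescaled together by median-of-ratios factors over the 12194 identifiers above 1 FPKM in every column. The factors lay between 0.922 and 1.06. Identifiers with at least 1 rescaled FPKM in at least 2 columns were kept, which left 15420. Of these, 600 have values identical to those of another identifier in all 12 columns, as happens when copies share reads, and their levels are uncertain. An exact 0 can be a failed estimate, so a gene is only said to be listed at 0. Changes are on the scale of log2(FPKM + 1), which understates changes of low genes.

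The planned tests used replicate libraries and could not be run, because each group has 1 value. A difference between the temperatures on a single day is therefore a comparison of 2 values with no error and no test. Genes were counted when these differed by at least 1 on the log2 scale. The temperature effect was tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean trend) over the 12 columns, with day and temperature as terms. Its spread is that of the 35 minus 25 difference between the 6 days. The change over storage was tested with limma as the mean of days 5, 6 and 7 minus that of days 1, 2 and 3, in 4 groups of 3 days. Its spread is that between the 3 days of a period at one temperature, so it contains any change within the period. P-values from both fits measure spread between days, not between fruit or libraries. They were adjusted by Benjamini-Hochberg over all 15420 genes and called under 0.05. Each temperature lies in its own table, and whether the tables were normalized together is not given in the sources used here. A factor that differs between the tables stays in the temperature effect but cancels in the changes over storage.

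The fits were tested on simulated data of 15420 genes, of which 200 were changed in each comparison. The noise had each gene's observed spread and was drawn independently for each gene and column. Except in the fits with day as a term, simulated levels had no changes from day to day shared by the temperatures. The recovered shares hold for such data and could differ in the real columns. For the temperature effect, 60% of genes changed 2-fold and 92% of those changed 4-fold were called. For late minus early storage the shares were 28% and 80.0% at 25 °C, and 31% and 85% at 35 °C. For the difference of these changes they were 5% and 53%, and 1% and 46% in an alternative fit with day as a term.

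The tables hold identifiers without gene names or descriptions, and 0 of them matched the RefSeq gene table used here for names. The 32 lists of gene families written before the data were examined, such as heat shock proteins, ethylene synthesis, pectin degradation and markers of green, vascular and epidermal tissue, rest on product descriptions and matched 0 identifiers. No list was tested. Genes are given by identifier, without genome positions. By the rule fixed for identifiers without descriptions, the 2 genes with the largest rise and the 2 with the largest fall are named for the temperature effect. They had to be called, to have the same sign on all 6 days and to have a mean of at least 5 FPKM at the temperature with the higher level. Alternatives were another pseudocount, other filters, other scalings, other ways of grouping days, each day left out in turn and other treatments of repeated or identical rows.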

Results

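RNA abundance was measured in the flesh of harvested peach fruit stored at 25 °C, the common condition, or at 35 °C, the high temperature. Sampling took place on days 1, 2, 3, 5, 6 and 7. Each of the 12 combinations of temperature and day is represented by 1 FPKM value per gene, standing for 2 libraries. No spread between replicates could therefore be given for any value. Read depth was unknown, and the FPKM sums of the columns ranged from 651850 to 882184. Of 26873 gene identifiers, 15420 passed the filter. The 10 most abundant identifiers took between 13.1% and 19.0% of the summed FPKM in each column. Prupe.4G009800, singled out after its values were seen, was the most abundant identifier on days 2 to 7 at 25 °C and on days 5, 6 and 7 at 35 °C, and reached 5.95% of the total on day 3 at 25 °C. The same identifier was listed at 0 on day 2 at 35 °C, although the other days at 35 °C ranged from 9570 to 31755 FPKM.

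The first question was how the 12 profiles related to temperature and storage time. The 2 profiles of day 1 lay close together, and the temperatures lay apart on every later day. Across genes, the Pearson correlation between 25 and 35 °C was 0.971 on day 1. It was 0.899 on day 2, 0.933 on day 3, 0.944 on day 5, 0.940 on day 6 and 0.946 on day 7. These are correlations across genes, which are not independent replicates. The first principal component held 40.2% of the variance and placed both day 1 profiles at one end, at -74.5 for 25 °C and -76.0 for 35 °C. The second held 23.0%. On it, days 2 to 7 at 35 °C scored between 10.9 and 48.1 and days 2 to 7 at 25 °C scored between -44.5 and -21.6.

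**Figure D1:**
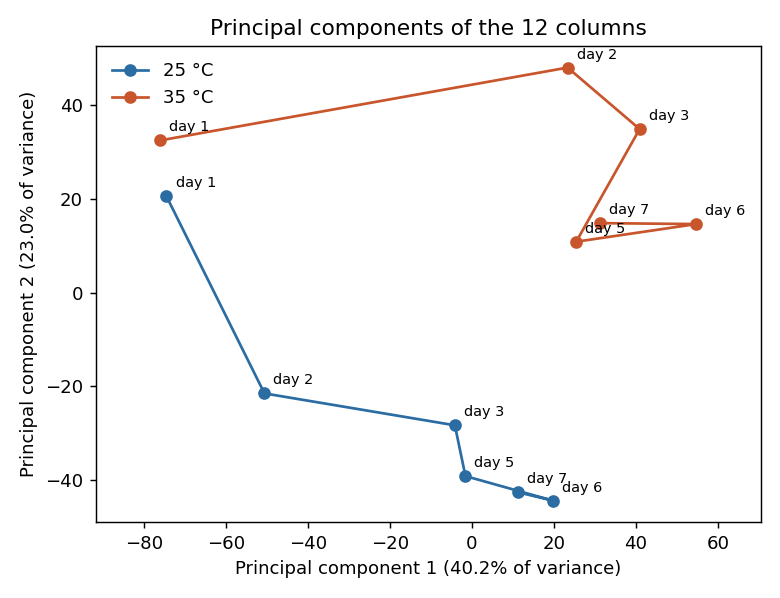
Scores of the 12 profiles on the first and second principal components of log2(FPKM + 1) over 15420 genes, with 40.2% and 23.0% of the variance on the axes, points for temperature and day combinations and lines joining successive days. The 2 points of day 1 lie together, and from day 2 the 35 °C points lie above the 25 °C points on the second component.

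The comparison of temperatures on each day asked when flesh stored at 35 °C came to differ from flesh stored at 25 °C. On day 1, 630 genes differed by at least 2-fold, 113 higher and 517 lower at 35 °C, which was 4.09% of genes. On day 2 the number was 3247, or 21.1%, with 1458 higher and 1789 lower at 35 °C. It was then 2129 on day 3 (1064 higher, 1065 lower), 2061 on day 5 (918 higher, 1143 lower), 1740 on day 6 (848 higher, 892 lower) and 1666 on day 7 (934 higher, 732 lower). A group of 118 genes was at least 2-fold higher at 35 °C on all 5 days from day 2 to day 7, and 113 genes were at least 2-fold lower on all 5. If the days were independent, 0.02 and 0.0252 genes would be expected, but the days share any lasting difference of a gene between the temperatures or the tables. In contrast, 604 genes were at least 2-fold higher and 784 at least 2-fold lower on day 2 and on no later day. These counts compare single values and have no test. Which direction held more genes depended on the processing on days 2, 3, 5 and 6: with FPKM as deposited, day 2 had 2006 higher and 1415 lower (the median gene moved from 0.03 to 0.19 on the log2 scale) and day 6 had 964 and 797, and with a pseudocount of 0.1 day 5 had 1642 and 1532, while more genes were lower on day 1 and higher on day 7 in each alternative.

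**Figure D2:**
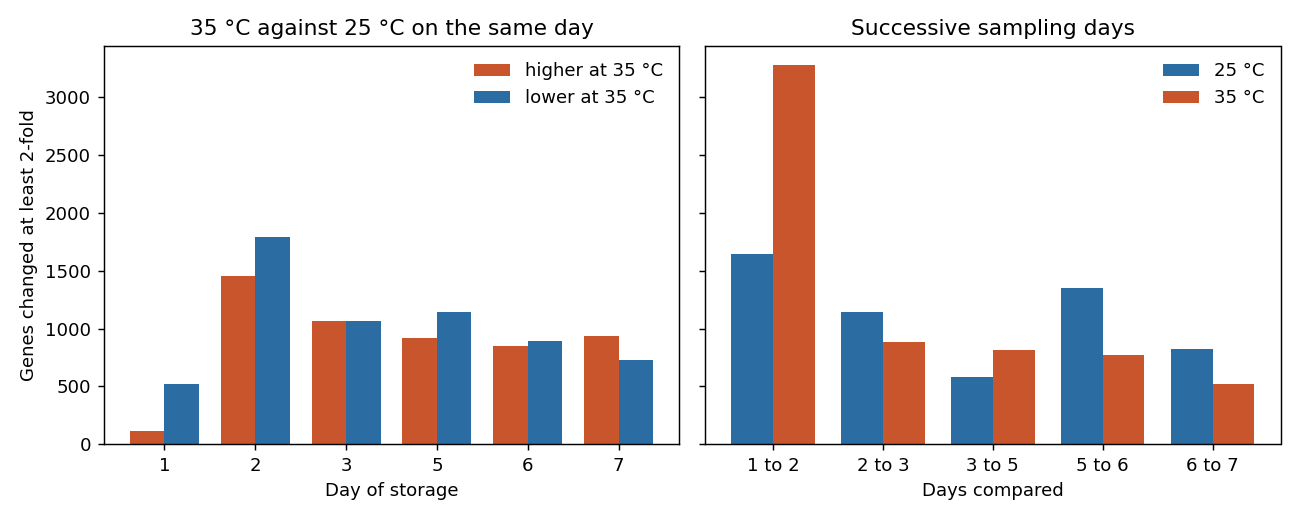
Number of genes that differed by at least 2-fold between 35 and 25 °C on the same day (left, by direction) and between successive sampling days at each temperature (right), as counts out of 15420 genes from single values, with no error. The tallest bars are day 2 on the left and the step from day 1 to day 2 at 35 °C on the right, with 3281 genes.

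The mean temperature effect asked which genes were higher or lower at 35 °C across the 6 days. In limma, with the spread between days as the error, 1849 of 15420 genes were called at an adjusted p under 0.05, 958 higher and 891 lower at 35 °C. Of these, 630 differed by at least 2-fold on average, and 277 of the 630 were higher at 35 °C. An unadjusted p under 0.05 was reached by 5081 genes, where 771 would be expected by chance. The smallest limma adjusted p was 0.0187, so that all calls lay between this value and 0.05. The balance of directions depended on the processing, with 1106 higher and 700 lower for FPKM as deposited, and 497 higher and 719 lower among genes with a mean of at least 5 FPKM. The sign was the same on all 6 days in 692 of the 958 higher genes and in 716 of the 891 lower genes. The test itself favours such genes, because its error is the spread of the difference between days. Among all tested genes 19.4% had one sign throughout, against 3.12% expected from coin flips. The days are not independent, because they share any lasting difference of a gene between the temperatures or the tables. Genes called higher had a median difference of 0.17 on the log2 scale on day 1 and of 1.04 on day 2, 0.97 on day 3, 0.87 on day 5, 0.85 on day 6 and 0.79 on day 7. Genes called lower had medians of -0.30, -1.05, -1.02, -1.03, -0.95 and -0.84 on the same days. These medians come from the values by which the genes were called and add no support to the calls.

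The genes with the largest mean rise at 35 °C were Prupe.1G498300 and Prupe.1G498600, which had identical values in all columns and count as 1 measurement. Their mean was 39.5 FPKM at 25 °C and 313 FPKM at 35 °C, a log2 change of 2.84 ± 0.52 (SE over 6 days, limma adjusted p = 0.0236). The difference was small on day 1, at 98.0 FPKM against 106 FPKM at 35 °C. On day 2 the values were 55.0 FPKM at 25 °C and 916 FPKM at 35 °C, and on day 6 they were 17.0 FPKM and 286 FPKM. The largest fall was that of Prupe.4G261900, from a mean of 51.6 FPKM at 25 °C to 1.76 FPKM at 35 °C, a log2 change of -4.10 ± 0.51 (limma adjusted p = 0.0187). It was lower at 35 °C on 6 of 6 days, with log2 differences between -5.91 and -1.18. Prupe.6G141100, one of the most abundant transcripts, averaged 9288 FPKM at 25 °C and 1081 FPKM at 35 °C, a log2 change of -3.74 ± 0.55 (limma adjusted p = 0.0205). It was listed at 5885 FPKM and 4000 FPKM on day 1. By day 2 it stood at 19134 FPKM at 25 °C and 1306 FPKM at 35 °C, and by day 7 at 3550 FPKM and 231 FPKM. The 2 temperatures lie in separate tables, and the count of called genes depended on single days. Without day 1 it was 3006, without day 2 it was 211, without day 6 it was 1, without day 7 it was 129, and without day 3 or day 5 it was 0. The direction of these 4 genes was the same in each case, but none of the 4 stayed called without day 3, 5 or 6. Their limma adjusted p then lay between 0.0686 and 0.0776.

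**Figure D3:**
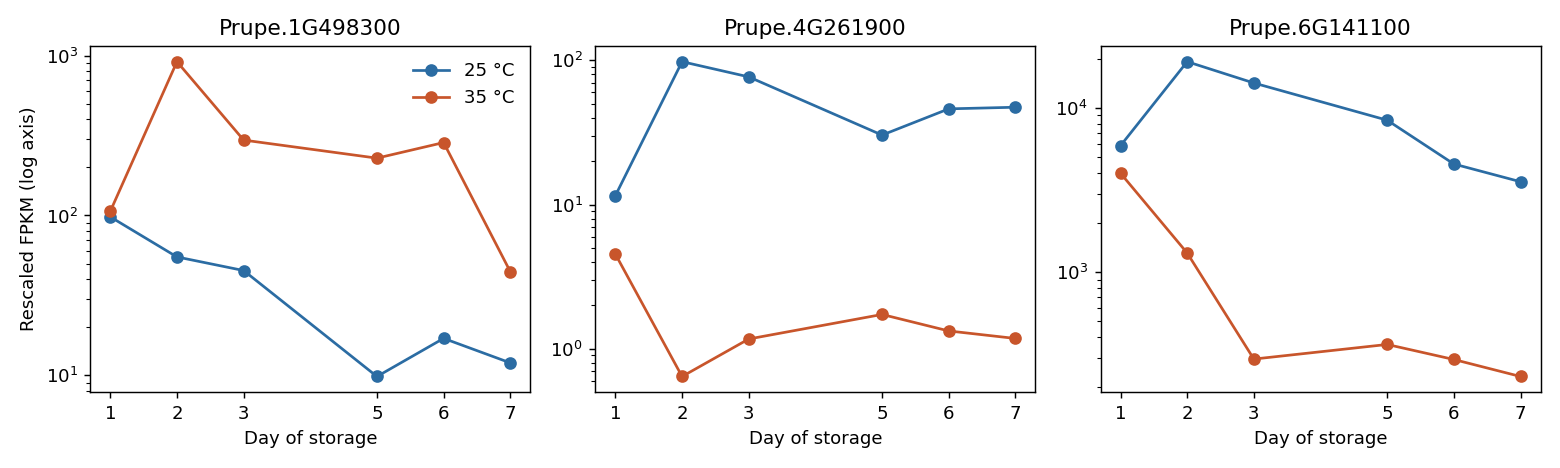
Rescaled FPKM (log axis) against day of storage for Prupe.1G498300, Prupe.4G261900 and Prupe.6G141100 at 25 and 35 °C, with points for the single value of each temperature and day and no error. From day 2 to day 7 the 2 lines do not cross.

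The change over storage at 25 °C was examined as days 5, 6 and 7 against days 1, 2 and 3. No gene passed the test against the spread of days within a period, with 0 genes called by limma. An unadjusted p under 0.05 was reached by 1614 genes, where 771 would be expected by chance, and the smallest adjusted p was 0.0616. By a linear slope on day, fitted with limma after the data were seen, 286 genes were called at 25 °C, 66 rising and 220 falling. Late minus early called 126 genes without day 3, 8 without day 5 and 1 without day 1. Between successive days at 25 °C, the number of genes that differed by at least 2-fold was 1648 from day 1 to 2, 1143 from day 2 to 3, 579 from day 3 to 5, 1350 from day 5 to 6 and 825 from day 6 to 7. From day 1 to day 7, 640 genes were at least 2-fold higher and 2007 at least 2-fold lower.

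At 35 °C the same comparison called 1 gene, Prupe.6G210900, named after its values were seen because it was the single call. It averaged 21.0 FPKM on days 1 to 3 and 5.71 FPKM on days 5 to 7, a log2 change of -1.70 ± 0.20 (SE, limma adjusted p = 0.0407). At 25 °C its means were 23.2 FPKM and 23.4 FPKM. Leaving out day 1, 5, 6 or 7 gave 0 calls and leaving out day 3 gave 72. Leaving out day 2 gave 1 call, a rise, and so of another gene. Prupe.6G210900 stood at 26.0 FPKM and 17.5 FPKM on days 1 and 3 at 35 °C, and between 5.47 FPKM and 6.18 FPKM on days 5 to 7. An unadjusted p under 0.05 was reached by 1294 genes at 35 °C, and the linear slope called 39, of which 8 rose and 31 fell. The step with the most 2-fold differences at 35 °C was day 1 to day 2, where 1607 genes were at least 2-fold higher and 1674 lower on day 2. The later steps held 882, 818, 775 and 517 such genes. From day 1 to day 7 at 35 °C, 1260 genes were at least 2-fold higher and 1856 lower.

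Whether the change over storage differed between the temperatures was tested as the difference of the late-minus-early changes. No gene was called by limma (0 of 15420), 471 reached an unadjusted p under 0.05 where 771 would be expected by chance, and the smallest adjusted p was 1.00. With day as a term, so that the spread was that of the within-day differences, limma also called 0 genes, with 673 at an unadjusted p under 0.05 and a smallest adjusted p of 0.953. In simulated data with independent noise, the fit without day recovered 53% of 4-fold and 5% of 2-fold differences of this kind. The fit with day recovered 46% and 1%, so that most 2-fold differences in such data were missed by either. These shares could differ in the real columns, and the 0 calls do not show that the courses were alike.

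The courses were also compared gene by gene from day 1 to the mean of days 5, 6 and 7, with no column shared between the temperatures. At 25 °C, 553 genes were at least 2-fold higher and 1738 lower, and at 35 °C 1189 were higher and 1775 lower. Of these, 298 were higher at both temperatures and 1164 lower at both, where independent lists would share 42.6 and 200. Opposite changes of at least 2-fold were found in 45 genes, 9 higher at 25 °C and 36 higher at 35 °C. Genes at least 2-fold lower at 25 °C had a median change of -1.65 there and of -1.48 at 35 °C, on the log2 scale. For genes at least 2-fold higher at 25 °C the medians were 1.37 and 1.12. Because the genes were chosen by their change at 25 °C, the medians there are raised in size. They do not show a weaker change at 35 °C. The correlation of changes across genes was 0.727. Over the single step from day 1 to day 2 it was 0.292, with 223 genes higher and 398 lower at both temperatures and 162 opposite.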

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

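Alternatives that leave out a day, fit a slope, use 4 groups of days for the temperature effect, keep rows apart, add day as a term to the difference of the changes, drop genes listed at 0 or count identical values once were chosen after the data were examined. The comparisons were planned, but testing them with days as units was chosen once each group was seen to have 1 value. No paired analysis was possible because the columns carry no replicate number, though the temperature effect was paired by day. No replicate could be left out, and alternatives for gene lists were not run because no list matched. The temperature effect already uses all columns, so no fit of the compared groups alone was run, and day 7 against day 1 has no test, only the 2-fold counts. The 1849 genes called between the temperatures became 397 with no filter on low values, 1216 with a mean of at least 5 FPKM and 1214 with 4 groups of temperature and period, and ranged from 0 to 3006 when 1 day was left out. The other 6 alternatives gave 1472 to 1926. Of the 1849, 1657 were called the same way as deposited and 1322 with quantile normalization. The 4 named genes kept their direction in each alternative in which they were fitted, but Prupe.1G498300 and Prupe.1G498600 lost the call with no filter (limma adjusted p = 0.0511, range over the alternatives 0.00181 to 0.0776) and without day 2, 3, 5, 6 or 7. Prupe.4G261900 and Prupe.6G141100 lost it without day 3, 5 or 6, with limma adjusted p up to 0.0771 from 0.000716. Without 1 day their log2 changes stayed between 2.53 and 3.39 for the rises, -4.68 and -3.73 for Prupe.4G261900 and -4.38 and -3.37 for Prupe.6G141100. With a pseudocount of 0.1, more genes differed by at least 2-fold between the temperatures on each day. The counts were 1014 on day 1, 4537 on day 2, 3148 on day 3 and 3174 on day 5. On day 6 the count was 2784 (1487 higher), and on day 7 it was 2776. With a mean of at least 5 FPKM the counts fell, to 415 on day 1 and 2326 on day 2. For late minus early at 25 °C, calls were 4 with no filter, 1 with the stricter filter, 2 as deposited, 2 with rows kept apart and 286 by slope, and 0 to 126 without 1 day. At 35 °C they were 2 with a pseudocount of 0.1, 2 with no filter, 3 with the stricter filter, 4 each as deposited, with quantile normalization, without genes listed at 0 and with identical values counted once, 0 with rows kept apart or with the 35 °C columns alone, 39 by slope, and 0 to 72 without 1 day. The difference between these changes had 1 call with no filter and 0 otherwise, including with day as a term. The causes were not tested. Read depth, and so what it limits, is unknown.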

Other observations

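The tests below that compare days, scalings, columns or neighbouring genes were chosen after the results they bear on had been seen, and the tests on other splits of the columns were set out before their results were seen. At 25 °C, 14267 identifiers were listed at 1 FPKM or more on day 1 and 13481 on day 7. At 35 °C the numbers were 14260 on day 1, 14433 on day 2 and 13766 on day 7. Abundance classes differed in the direction of the calls between temperatures. Genes with a mean under 5 FPKM had 441 higher and 155 lower at 35 °C, those of 5 to 50 FPKM 426 and 433, those of 50 to 500 FPKM 84 and 282, and those of 500 FPKM or more 7 and 21. With quantile normalization the class under 5 FPKM had 263 higher and 193 lower and that of 5 to 50 FPKM 383 and 340, and the last classes turned round, with 149 higher and 115 lower among genes of 50 to 500 FPKM and 17 and 12 among the most abundant, while FPKM as deposited gave 107 and 218, and 8 and 15. FPKM as deposited gave 479 higher and 137 lower in the class under 5 FPKM and 511 and 329 in that of 5 to 50 FPKM. The balance of directions therefore depends on the scaling, though under 5 FPKM more genes were higher than lower at 35 °C with each scaling.

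Of the 32 ways to swap the temperatures within days, 1, the real arrangement, reached 1849 calls. The highest other gave 812, when day 1 alone was swapped. A share of 1 in 32 is the smallest that these swaps can give. At this limit, differences whose direction varied at random from day to day are unlikely to account for the count. The swaps treat days as independent, and no replicate values exist. They cannot tell temperature from any other difference between the fruit of the 2 temperatures that lasted over several days. A constant factor per gene between the 2 tables is argued against by the 3006 genes called without day 1, whose median difference in the called direction was 0.07 on day 1 (quartiles -0.15 and 0.28) and 0.85 over days 2 to 7, so that day 1 held 7.74% of the later difference. Scaling of whole columns, or a few abundant genes taking most of the signal, is argued against as the whole cause only. The median change of the called genes kept 94.5% of its size after quantile normalization, and 71.5% of them were called the same way. Because 958 genes were called higher and 891 lower, a shift of whole columns could leave this median little changed. A part due to scaling therefore stays open. A response to temperature stays open, as a hypothesis.

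From day 1 to day 2 at 35 °C, 3281 genes changed at least 2-fold. On days 3 to 7, measured from day 1 at 25 °C, the same genes held 71.1% of the change at 35 °C (median 1.02 of 1.43, quartiles 0.53 and 1.70, 91.5% with the same sign) and 39.9% at 25 °C (median 0.57, quartiles 0.13 and 1.27, 80.7% with the same sign), which argues against a fault of the day 2 column as the whole cause, while a fault behind part of the change stays open, since the 35 minus 25 difference on those days had a median of 0.33 (quartiles -0.03 and 0.78). A candidate explanation is that 35 °C brought forward the changes seen at 25 °C: by days 5 to 7, 32.9% of these genes were at least 2-fold changed the same way at 25 °C and 3.84% the opposite way (quartiles 0.10 and 1.31), against 48.3% the same way at 35 °C (quartiles 0.46 and 1.67). Correlations across genes go both ways. Day 2 at 35 °C correlated best with day 3 at 25 °C (0.930, against 0.899 with the same day). Day 5 correlated best with day 7 (0.949, against 0.944 with the same day). In contrast, day 3 correlated best with day 3, day 6 with day 6 and day 7 with day 5 (0.949, against 0.946 with the same day). For days 5 and 7 at 35 °C these are near ties, and no correlation has an error. Genes changed at least 2-fold at 25 °C by days 5 to 7 had medians of 0.92 at 35 °C and 0.89 at 25 °C on day 2. On day 7 the medians were 1.36 and 1.72. Choosing genes by their change at 25 °C raises the medians there, so these medians cannot decide the question. That 35 °C brought forward the changes seen at 25 °C stays open, as does a response to 35 °C of its own.

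With day 1 set against the other 5 days, limma called 0 genes for a different temperature effect. An unadjusted p under 0.05 was reached by 1347 genes, where 771 would be expected by chance, and the smallest adjusted p was 0.142. With no filter on low values it called 62. With day 2 singled out in the same way 6 genes were called, with day 7 1 gene, and with day 3, 5 or 6 0 genes. Each of these fits sets a single difference per gene against 5 others, and recovery was not simulated for them. The 0 calls therefore do not show that a day was like the others.

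For late minus early storage at 25 °C, all 10 splits of the 6 days gave the 0 calls of the real one, which could not have been otherwise with 0 real calls, and the highest other was 0. At 35 °C 1 of 10 splits gave as many as the real one, with 1 call against 0 in the highest other. With 10 splits no share under 0.05 can be reached. For the difference of these changes, the real columns gave 0 calls, so that each of the 32 swaps had to give as many and the count says nothing about chance. The highest other, 1214, came from swapping days 5, 6 and 7, which turns the contrast into the temperature effect and points to a structure of the samples.

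Called genes lay next to each other in the table more often than in shuffled order. With identical values counted once, 174 neighbouring pairs were called in the same direction, against a mean of 107 and a highest value of 140 in 1000 shuffles (permutation p = 0.001, one-sided, the smallest these can give). A candidate explanation is that neighbouring identifiers are copies of one family that change together or share reads in part, and the test does not separate these. Prupe.3G012200 and Prupe.3G012400 were listed at 0 on day 1 at 25 °C and reached 247 and 239 FPKM on other days at 25 °C. Together with Prupe.4G009800 on day 2 at 35 °C, these were the 3 identifiers listed at 0 beside values of at least 10 FPKM on every other day of the same temperature.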
